A study of Mus musculus with 6 samples.

How the data were processed

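The series measured RNA of mouse tumour neutrophils in 3 GPR35-negative and 3 GPR35-positive libraries, grouped and numbered by their titles. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with the NEBNext Ultra II RNA kit. How cells were sorted, and whether replicates were separate animals, is not given in the sources used here. The authors deposited 1 table of FPKM, per the file headers; FPKM are fragments scaled to gene length and to the reads of the library. The submitters' processing notes name fastp 0.22.0, HISAT2 2.1.0, HTSeq 0.9.1 and DESeq 1.38.3 without their roles, and the human build GRCh38, while the table holds mouse Ensembl gene IDs. The annotation is not given in the sources used here.

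Gene symbols, positions and exon lengths were taken from GENCODE M21, built on GRCm38, in which 21851 of 21959 IDs had an entry; the other 108 kept their ID. With those lengths, 97.7% of FPKM values above 0 came out as whole reads within 0.02 reads, and so did all values of 19309 of the 19818 genes above 0. The total of reads assigned to genes in each library was read from these steps and ranged from 15742744 to 18314104. At that depth 1 read on a gene of 1 kb is worth 0.0546 to 0.0635 FPKM. Replicates of a group differed by more than sampling noise, with a mean chi-square per gene of 5.1 to 20.2 over 11578 genes, so none was treated as a duplicate.

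The plan fixed before the data were examined named a count-based test, with limma-trend for the case that only normalized values were held. The table holds FPKM, so the main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(FPKM + 1), two-sided, with group as the only term and Benjamini-Hochberg adjustment over all genes tested at 0.05. Genes with at least 1 FPKM in at least 3 libraries were tested. Adjusted p-values are from limma throughout unless another test is named. Fold changes called log2 are on the log2(FPKM + 1) scale, which understates the change of low genes; other folds are ratios of mean FPKM. Levels are means ± SD over 3 libraries. Reads of near-identical genes, such as the Bcl2a1, H2 and C1q families, and of overlapping genes may have been split or lost in the authors' counting, and whether it used strand is not given in the sources used here.

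Gene lists were tested with limma's camera at a preset correlation of 0.01, with a correlation estimated for each list, and with fry, each adjusted over 31 lists. The groups, the lists, the test, the alternatives other than those named as added, and the rule for named genes were chosen before the data were examined. That rule takes Gpr35, the 12 largest rises and the 12 largest falls among genes past the threshold with a mean log2 CPM of at least 2 and fully separated groups, up to 4 members of each list with the smallest p, and 20 focus genes. Predicted genes, pseudogenes and receptor segments were left out of the largest changes. List members named as exceptions, and the most abundant genes, were chosen after their values were seen. A few genes that the rule or the lists take are not reported here.

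The test was tried on simulated data for the same 6 libraries, with 10053 genes of which 200 were changed. It recovered 92% of 100 genes changed 1.5-fold and 99% of 100 changed 2-fold, and called 10 unchanged genes. The simulation used a single dispersion of 0.00487, taken from the GPR35-negative libraries, and raised as many genes as it lowered. In the data 68.8% of genes tested passed, with rises larger than falls, so these rates may not carry over. Alternatives were another pseudocount, other filters, median-of-ratios scaling, scaling without mitochondrial and the 50 most abundant genes, limma-voom on the recovered reads, a replicate block, a 2-fold minimum and leaving out each library. A trend on GC content and length was removed as an alternative added after the data were seen. The deposited unit is FPKM, so limma-voom on the recovered reads was the only count-based test run, and the other planned ones were left out. Scaling to library totals is what the deposited FPKM already hold. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. All 6 value columns of the table were used.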

Results

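RNA was sequenced from mouse neutrophils of tumours of Hepa1-6, a mouse hepatoma cell line, after they had been divided by GPR35, a G protein-coupled receptor. The series holds 6 libraries, 3 labelled GPR35-negative and 3 labelled GPR35-positive. The deposited FPKM values cover 21959 genes, of which 19818 were above 0 in at least 1 library. The GPR35-negative libraries held 17244562, 16943517 and 15742744 reads assigned to genes, and the GPR35-positive libraries 17132645, 16329518 and 18314104, as read from the steps between low FPKM values. Nothing in the labels says that replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical. The comparison asks how libraries labelled GPR35-positive differed from those labelled GPR35-negative. Hepatocyte and hepatoma markers summed to 26450 FPKM in GPR35-negative and 17420 FPKM in GPR35-positive libraries, against 1011 and 9781 FPKM for mature neutrophil markers. A difference between the libraries is therefore not by itself a difference between neutrophils.

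Gpr35 itself, the gene that the labels name, was higher in every GPR35-positive library. Its level was 1.57 ± 0.398 FPKM (SD, n = 3) in GPR35-negative and 20.2 ± 1.89 FPKM (SD, n = 3) in GPR35-positive libraries, 12.9-fold higher. The log2 fold change was 3.05 (SE 0.12, adjusted p = 6.27e-09). Summed mature neutrophil markers were 9.68-fold higher in the same libraries, so the Gpr35 rise alone cannot check a division by GPR35. The gene, ENSMUSG00000026271, lies on the forward strand of chromosome 1 from 92950865 to 92986391 in GRCm38. It was covered by 169, 113 and 99 reads in the GPR35-negative libraries and by 1506, 1732 and 1810 reads in the GPR35-positive ones. The exact 95% Poisson intervals, which cover counting error only, ran from 80.5 to 196 reads over the GPR35-negative libraries and from 1431 to 1895 over the GPR35-positive ones.

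Myeloid transcripts were far higher in GPR35-positive libraries, while the abundant transcripts of hepatocytes and hepatoma cells were present in all 6 libraries and lower in the GPR35-positive ones. S100a8, a neutrophil alarmin subunit, rose from 517 ± 46.8 to 5262 ± 406 FPKM, and C1qb, a chain of complement C1q made mainly by macrophages, rose from 8.61 ± 1.84 to 307 ± 23.6 FPKM (SD, n = 3 each). The transferrin gene Trf, a liver transcript with the highest mean level of all genes tested, fell from 10850 ± 288 to 7130 ± 194 FPKM. Of 10060 genes tested, 2342 were higher and 4575 lower in GPR35-positive libraries, and 3143 did not pass the threshold. The rises were large and the falls small: 1108 genes were at least 2-fold higher and 21 at least 2-fold lower, and 141 were at least 8-fold higher and 0 at least 8-fold lower. Groups were fully separated in 72.5% of the genes tested, against the 10% that chance gives for 3 against 3. The median log2 fold change of all genes tested was −0.19, and with median-of-ratios scaling, which moved it to −0.03, 2913 genes were higher and 2401 lower, so that 54.8% of calls were higher against 33.9% as deposited.

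**Figure D1:**
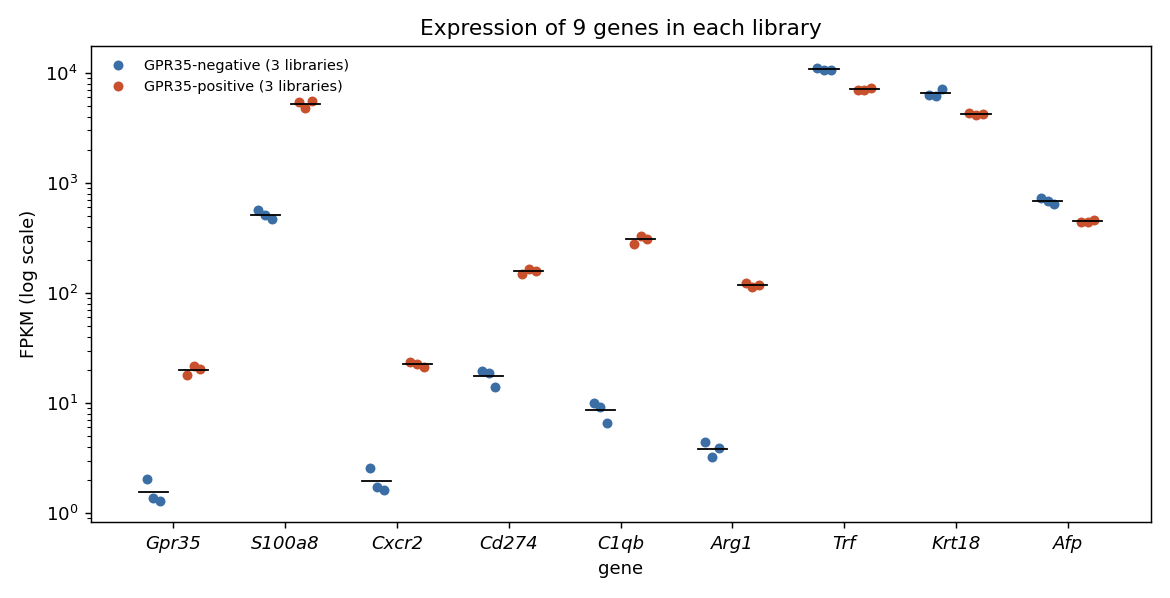
FPKM on a log axis of 9 genes in each of the 3 GPR35-negative (blue) and 3 GPR35-positive (red) libraries; points are libraries and bars are means. Gpr35, S100a8, Cxcr2, Cd274, C1qb and Arg1 are higher in every GPR35-positive library, and Trf, Krt18 and Afp are lower in every one.

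Among genes with a mean of at least 2 on the log2 CPM scale and fully separated groups, the 12 largest rises were led by complement and macrophage transcripts. C1qb rose by a log2 fold change of 5.02 (SE 0.13, adjusted p = 7.2e-10), and C1qa and C1qc by 4.84 and 4.83. The chemokine genes Ccl24, Ccl8 and Ccl12 rose by 4.84, 4.43 and 4.25. The matrix metalloproteinase genes Mmp12 and Mmp13 rose by 4.64 and 4.44, the cathepsin genes Ctss and Ctsc by 4.65 and 4.53, and Cd83, a surface marker of activated antigen-presenting cells, by 4.16. Arg1, which encodes the arginine-degrading enzyme arginase 1, rose from 3.84 ± 0.623 to 118 ± 4.19 FPKM (SD, n = 3 each), 30.7-fold.

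The 12 largest falls were all between 1.04 and 1.17 in size on the log2 scale. They included Hnf4a and Gata4, transcription factors of liver and endoderm, the laminin gene Lama5, the epithelial integrin gene Itgb4, the polarity gene Llgl1, Foxq1, Ephb4, Kank2, Lzts2, Sowahb, Vars and Igfbp4. Hnf4a fell from 23.0 ± 4.46 to 10.4 ± 1.78 FPKM (SD, n = 3 each, adjusted p = 0.000142), and Igfbp4 from 256 ± 22.2 to 117 ± 26.5 FPKM. The genes at least 2-fold lower had a median GC content of 57.7%, against 50.7% for all genes tested, among the 20 with a GC value. Their number, 21, was 7 without GPR35-negative replicate 2, 42 without GPR35-negative replicate 3, 2 without GPR35-positive replicate 1 and 54 without GPR35-positive replicate 2. It was 82 with a pseudocount of 0.1, 108 with limma-voom, 5 with a GC and length trend removed and 0 with median-of-ratios scaling. With the trend removed, the median log2 fold change of the 20 with a GC value moved from −1.05 to −0.95, and all 20 still passed the threshold.

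Markers of mature neutrophils rose together. Of 18 tested, 17 rose and 0 fell, with a median log2 fold change of 2.73, and the list differed from other genes with a camera adjusted p of 5.34e-14 (adjusted p = 0.119 with an estimated correlation). S100a9 rose from 245 ± 48.8 to 2493 ± 138 FPKM, the chemokine receptor gene Cxcr2 from 1.97 ± 0.519 to 22.6 ± 1.3 FPKM, and Ly6g, the gene of the antigen used to identify mouse neutrophils, from 0.947 ± 0.316 to 5.02 ± 0.674 FPKM (SD, n = 3 each). The formyl peptide receptor gene Fpr1, G0s2, Mxd1 and the gelatinase gene Mmp9 rose by 3.29, 3.38, 2.81 and 2.58 on the log2 scale. Padi4 was at 29.5 and 33.0 FPKM and did not pass (adjusted p = 0.0802). The summed level of the list was 1011 ± 114 FPKM in GPR35-negative and 9781 ± 478 FPKM in GPR35-positive libraries, 9.68-fold higher. Of 10 granule and precursor genes tested, 5 rose and 1, Prtn3, fell (adjusted p = 0.00733 by camera, and 0.285 with an estimated correlation). Without a filter 6 of 16 rose and 1 fell, with a median of 0.15 against 0.85 for the 10 tested. The summed level of that list was 1.07-fold higher in GPR35-positive libraries. Ltf, which encodes lactoferrin, Ngp, Cebpe and Chil3 rose by 2.15, 1.90, 1.67 and 1.37.

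**Figure D2:**
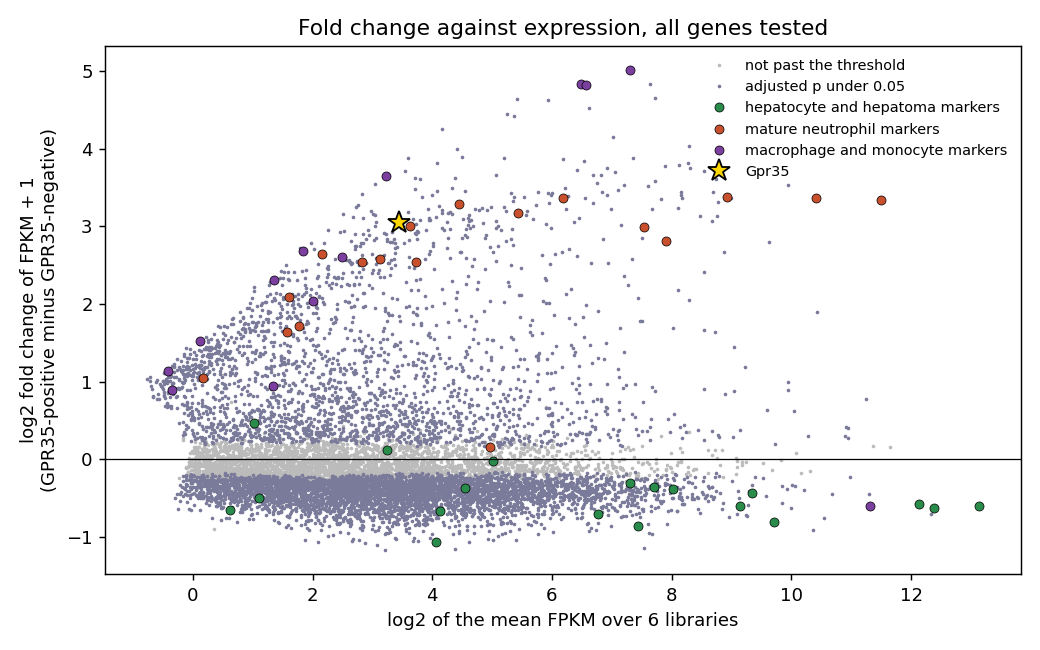
Log2 fold change of FPKM + 1 (GPR35-positive minus GPR35-negative) against the log2 of the mean FPKM for each gene tested; coloured circles are members of 3 cell type lists and the star is Gpr35. Gpr35, at 3.05, lies among the mature neutrophil markers, and most hepatocyte and hepatoma markers lie below 0.

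Genes described in long-lived tumour neutrophils and in suppressive myeloid cells rose in the same libraries as the neutrophil markers. Of 19 long-lived tumour neutrophil genes, 15 rose and 1, Tnfrsf10b, fell (camera adjusted p = 2.33e-08; adjusted p = 0.121 with an estimated correlation). Cd274, which encodes the checkpoint ligand PD-L1, rose from 17.5 ± 2.97 to 158 ± 7.77 FPKM, and the chemokine genes Ccl3 and Ccl4 by 3.71 and 3.37 on the log2 scale. Clec5a, Cxcr4 and Siglecf rose by 3.46, 1.89 and 1.37. Vegfa, which encodes an angiogenic growth factor, was at 4.12 ± 0.366 and 4.86 ± 0.469 FPKM (SD, n = 3 each) and did not pass (adjusted p = 0.0913). Vegfa passed with median-of-ratios scaling (adjusted p = 0.0108), without GPR35-positive replicate 1 (0.0446) and with a GC and length trend removed (0.0174). Of 14 suppressive myeloid genes, 11 rose and 1, Ptges, fell (camera adjusted p = 1.92e-07; adjusted p = 0.149 with an estimated correlation). Besides Arg1, these included Wfdc17, the interleukin 1 receptor antagonist gene Il1rn and the prostaglandin synthase gene Ptgs2, at 3.88, 3.02 and 2.98. Nos2 was below the filter, at 0.0859 to 0.209 FPKM in GPR35-negative and 0.704 to 0.923 FPKM in GPR35-positive libraries.

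Cytokine, interferon-stimulated and NF-kappaB feedback genes were also higher in GPR35-positive libraries. Of 19 inflammatory cytokine and chemokine genes, 17 rose and 0 fell (camera adjusted p = 1.5e-10; adjusted p = 0.121 with an estimated correlation), while Cxcl1 and Cxcl10 did not pass. Il1b rose from 50.1 ± 17.2 to 519 ± 55.3 FPKM and Tnf from 20.1 ± 2.57 to 222 ± 19.3 FPKM (SD, n = 3 each), and Cxcl2, Ccl7 and Csf1 rose by 3.14, 2.82 and 2.67 on the log2 scale. Of 23 type I interferon-stimulated genes, 20 rose and 2, Bst2 and Usp18, fell (camera adjusted p = 8.17e-11; adjusted p = 0.111 with an estimated correlation). The antiviral genes Isg15, Ifit3, Rsad2 and Ifit1 rose by 3.30, 2.92, 2.86 and 2.44. Of 15 NF-kappaB feedback genes, 14 rose and 0 fell (camera adjusted p = 1.76e-08; adjusted p = 0.149 with an estimated correlation), including Birc3, Rel, Nfkbia and Tnfaip3 at 2.67, 2.28, 1.90 and 1.86. The summed mature neutrophil markers differed 9.68-fold between the same libraries.

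Genes of arachidonic acid metabolism, matrix remodelling, the NADPH oxidase, G protein signalling and survival rose for the most part, in libraries whose summed mature neutrophil markers were 9.68-fold higher and whose C1qb was 35.6-fold higher. Of 14 arachidonic acid and leukotriene genes, 11 rose and 1, Ptges3, fell (camera adjusted p = 2.44e-07; adjusted p = 0.111 with an estimated correlation). These included the phospholipase genes Pla2g7 and Pla2g4a at 2.62 and 1.71 and Hpgds at 1.81, and the prostaglandin receptor gene Ptger2 rose from 1.01 ± 0.114 to 7.65 ± 0.876 FPKM (SD, n = 3 each). Of 19 angiogenesis and matrix genes, 11 rose and 4, Adamts1, Vegfb, Hbegf and Vegfc, fell (camera adjusted p = 0.00236; adjusted p = 0.179 with an estimated correlation). Mmp12 and Mmp13 rose most, and Prok2 and Sema4d rose by 3.22 and 2.85. Of 19 NADPH oxidase and antioxidant genes, 11 rose and 5 fell (camera adjusted p = 0.000457; adjusted p = 0.121 with an estimated correlation). The oxidase subunit gene Cyba, Rac2 and the cystine transporter gene Slc7a11 rose by 3.45, 2.46 and 2.33, the subunit gene Ncf4 rose from 4.95 to 46.5 FPKM, and the antioxidant genes Sod1, Nqo1, Prdx1, Gpx4 and Cat were those that fell. Of 22 G protein and arrestin genes, 14 rose and 4 fell, or 15 and 4 adjusted over the list alone (camera adjusted p = 0.000161; adjusted p = 0.111 with an estimated correlation). Rgs2, Rgs1, Gng2 and Gna13 rose by 2.95, 2.76, 1.76 and 1.54, and Gnb2, Gna11, Grk6 and Arhgef1 fell. Of 18 survival and apoptosis genes, 11 rose and 3, Xiap and Bid among them, fell (camera adjusted p = 0.000212; adjusted p = 0.121 with an estimated correlation), with the BCL2-family genes Bcl2a1a and Bcl2a1d at 3.85 and 3.31, Fas at 2.28 and Gadd45b at 2.25.

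Most macrophage, dendritic cell and granulocyte markers that passed the filter rose with the neutrophil ones, and a rise itself helps a low gene to pass it. Of 13 macrophage and monocyte markers tested, 12 rose and 1, Apoe, fell (camera adjusted p = 5.32e-09; adjusted p = 0.111 with an estimated correlation). Adgre1, which encodes F4/80, rose from 0.54 ± 0.167 to 18.2 ± 1.55 FPKM, and Csf1r, the receptor gene for macrophage colony-stimulating factor, from 0.858 ± 0.0721 to 10.4 ± 1.58 FPKM (SD, n = 3 each). Apoe, which hepatocytes also express, was at 3053 and 2013 FPKM and made up most of the list's summed level, so that the sum was 3077 ± 83.2 in GPR35-negative and 2734 ± 120 FPKM in GPR35-positive libraries. Of 18 antigen presentation genes, 16 rose and 0 fell, or 17 and 0 adjusted over the list alone (camera adjusted p = 2.03e-10; adjusted p = 0.119 with an estimated correlation). The class II genes H2-Ab1 and H2-Aa, the class I gene H2-K1 and Cd80 rose by 3.06, 2.98, 2.85 and 2.90. Of 24 phagocytosis and lysosome genes, 19 rose and 2, Axl and Ctsl, fell (camera adjusted p = 5.32e-09; adjusted p = 0.111 with an estimated correlation), with Cd68, Fcgr2b and Fcgr1 at 3.47, 2.73 and 2.28. Without a filter, 14 of 20 macrophage markers rose and 1 fell, with a median log2 fold change of 1.04 against 2.31 for the 13 tested. All 4 tested members of the dendritic cell list, Cd83, Batf3, Ccr7 and Bst1, rose, though Bst1 is not specific to dendritic cells. The list's camera adjusted p was 0.000432, and 0.111 with an estimated correlation. Without a filter 8 of 12 members rose, with a median of 0.43 against 1.71. All 4 eosinophil, basophil and mast cell markers tested, Ear2, Cpa3, Cma1 and Tpsb2, rose (camera adjusted p = 0.00204; adjusted p = 0.121 with an estimated correlation), and without a filter 7 of 15 did, with a median of 0.18 against 1.30.

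Hepatocyte, cell cycle and oxidative phosphorylation genes were lower in GPR35-positive libraries. Of 19 hepatocyte and hepatoma markers, 16 fell and 1, Serpina1a, rose (camera adjusted p = 0.00393; adjusted p = 0.231 with an estimated correlation). Alb, which encodes albumin, fell from 1068 ± 218 to 605 ± 53.2 FPKM, Afp, the alpha-fetoprotein gene, from 686 ± 49.7 to 450 ± 9.74 FPKM, and the keratin gene Krt18 from 6522 ± 531 to 4224 ± 109 FPKM (SD, n = 3 each). Gpc3 and Epcam fell by 0.86 and 0.70 on the log2 scale. The summed level of the list was 26450 ± 731 FPKM in GPR35-negative and 17420 ± 238 FPKM in GPR35-positive libraries, a ratio of 0.659. Of 22 cell cycle genes, 0 rose and 19 fell, with a median of −0.36 (camera adjusted p = 0.00378; adjusted p = 0.119 with an estimated correlation), among them Ube2c, Plk1, Mcm6 and Mcm3, which fell by 0.69, 0.59, 0.54 and 0.49. Of 27 oxidative phosphorylation genes, 0 rose and 19 fell (camera adjusted p = 0.0291, and 0.528 with an estimated correlation). Their median was −0.24, close to the −0.19 of all genes tested. The ATP synthase genes Atp5a1 and Atp5b fell by 0.54 and 0.51, and the complex I gene Ndufv1 by 0.51. The oxidative phosphorylation call ended with median-of-ratios scaling, which brought the list's median to −0.05 (adjusted p = 0.165), without GPR35-negative replicate 3 (0.0749) and without GPR35-positive replicate 2 (0.0886).

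Several metabolic lists held genes that moved in both directions, and none of these lists passed camera. In fry, the lipid handling, tryptophan and endoplasmic reticulum stress lists passed (adjusted p = 0.027, 0.00859 and 0.027), and the glycolysis and hypoxia list did not (adjusted p = 0.321). Of 26 glycolysis and hypoxia genes, 7 rose and 11 fell (camera adjusted p = 0.741), and their median was −0.18 while their mean was 0.12. The transporter genes Slc16a3 and Slc2a3 rose by 2.47 and 1.91, and Adm and Pfkp by 1.36 and 0.76. Of 24 lipid handling genes, 7 rose and 11 fell, or 7 and 12 adjusted over the list alone (camera adjusted p = 0.819), with a median of −0.23 and a mean of 0.16. The scavenger receptor gene Cd36, the cholesterol transporter gene Abcg1, the nuclear receptor gene Pparg and Mgll rose by 3.26, 2.55, 2.14 and 1.08. Of 12 tryptophan and aryl hydrocarbon receptor genes, 2, Slc3a2 and Tiparp, rose and 7 fell (camera adjusted p = 0.449). Cyp1a1, a target gene of the receptor, fell from 270 ± 65.7 to 136 ± 19.4 FPKM, and Aldh2 and Wars fell by 0.81 and 0.43. The ratios of mean FPKM were 0.51 for Cyp1a1 and 0.56 for Aldh2, beside 0.57 for Alb and 0.659 for the summed hepatocyte and hepatoma markers. Ahr was at 31.6 ± 9.07 and 28.1 ± 2.04 FPKM (SD, n = 3 each) and did not pass (adjusted p = 0.483). Of 18 endoplasmic reticulum stress genes, 4 rose and 9 fell (camera adjusted p = 0.819), with Chac1, Dnajb9 and Ppp1r15a at 0.99, 0.97 and 0.91 and Pdia4 at −0.61.

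**Figure D3:**
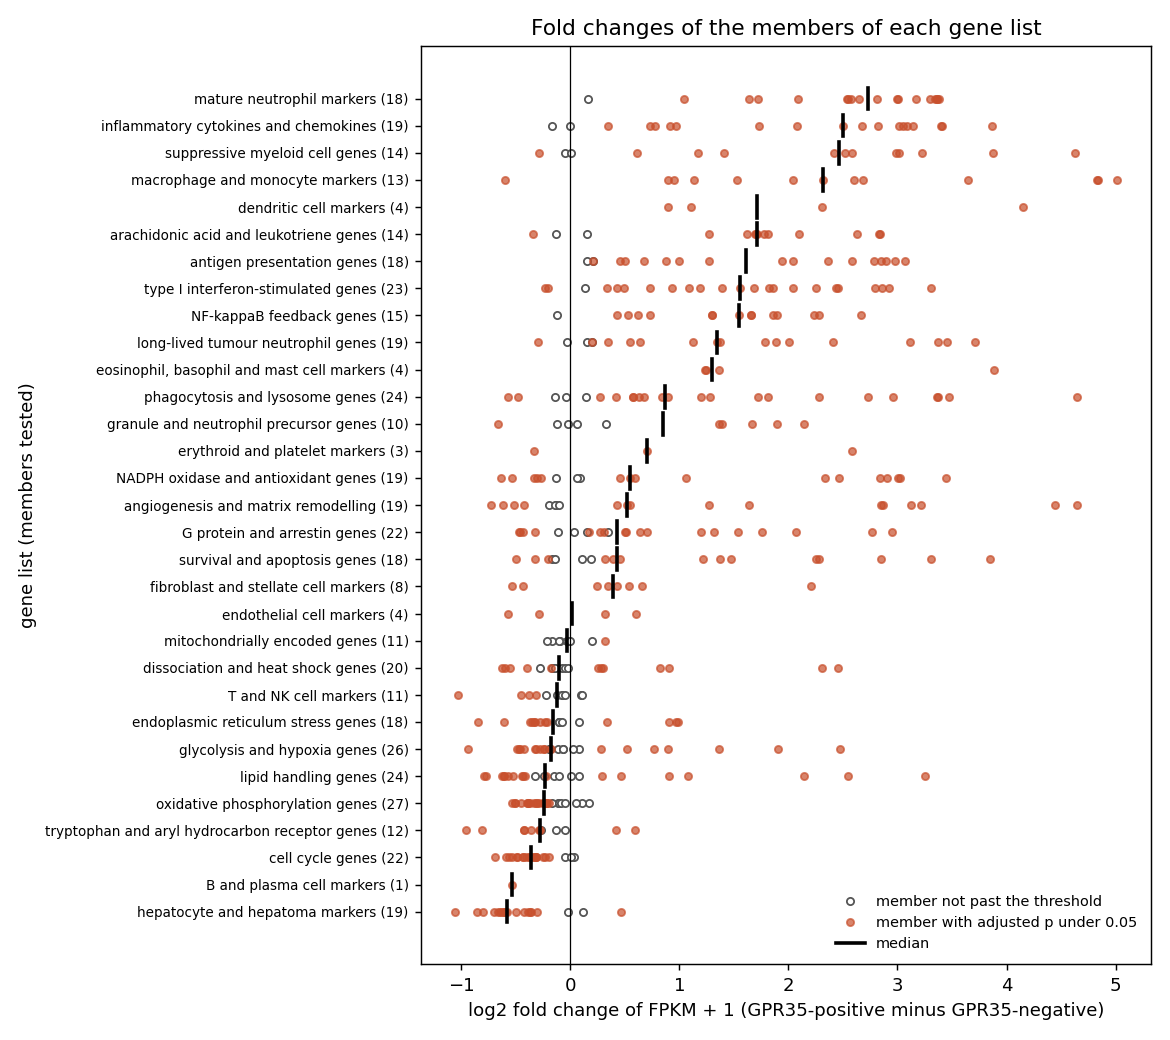
Log2 fold change of FPKM + 1 (GPR35-positive minus GPR35-negative) of each tested member of the 31 gene lists; filled points passed an adjusted p of 0.05, open points did not, and the black bar is the list's median. Medians run from −0.58 for hepatocyte and hepatoma markers to 2.73 for mature neutrophil markers.

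Lymphocyte markers did not rise with the myeloid ones. Of 11 T and NK cell markers tested, 0 rose and 4 fell (camera adjusted p = 0.426). Those were the cytotoxic genes Gzma, Gzmb and Prf1 and the kinase gene Lck, and Gzma fell from 14.5 ± 1.19 to 6.58 ± 0.181 FPKM (SD, n = 3 each). Prf1 and Lck did not pass with median-of-ratios scaling (adjusted p = 0.128 and 0.217), and Lck did not without GPR35-positive replicate 3 (0.0608). The 1 B and plasma cell marker tested, Sdc1, which epithelial cells also express, fell by 0.53 (camera adjusted p = 0.372). Of 4 endothelial markers tested, Eng and Pecam1 rose and Egfl7 and Esam fell (camera adjusted p = 0.705). Without a filter 7 of 14 rose and 1 fell, with a median of 0.11 against 0.01, and the list passed (camera adjusted p = 0.0218). Pecam1 did not pass without GPR35-negative replicate 2 or without GPR35-positive replicate 1 (adjusted p = 0.0734 and 0.0582). Esam did not pass without filter or with median-of-ratios scaling, nor without GPR35-negative replicate 1 or GPR35-positive replicate 2 (adjusted p = 0.0532, 0.33, 0.0874 and 0.0899). Of 8 fibroblast and stellate cell markers, 6 rose, including Acta2, Col1a2 and Bgn at 2.21, 0.66 and 0.35, and 2, Des and Sparc, fell (camera adjusted p = 0.0593). That list passed with a pseudocount of 0.1, without filter and with voom (adjusted p = 0.0489, 0.0193 and 0.046), and without GPR35-negative replicate 1 or GPR35-positive replicate 1 (0.0438 and 0.0376). Of 3 erythroid and platelet markers, Pf4 and Itgb3 rose and Ppbp fell (camera adjusted p = 0.15), and Ppbp did not pass with median-of-ratios scaling (adjusted p = 0.218). All 5 of these lists passed fry, the T and NK list and the 1 B and plasma cell marker on balance lower (adjusted p = 0.015 and 0.000461) and the endothelial, fibroblast, and erythroid and platelet lists on balance higher (0.0388, 0.00602 and 0.0003).

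Neither the dissociation and heat shock genes nor the mitochondrially encoded genes passed camera, while the dissociation and heat shock list passed fry, on balance higher in GPR35-positive libraries (adjusted p = 0.0017), and the mitochondrial list did not (adjusted p = 0.917). Of 20 dissociation and heat shock genes, 7 rose and 5 fell, or 6 and 4 adjusted over the list alone (camera adjusted p = 0.441), with a median of −0.11 and a mean of 0.20. The heat shock genes Hspa1a and Hspa1b rose by 2.45 and 0.91, and Egr2 and Zfp36 by 2.31 and 0.82. Of 11 mitochondrially encoded genes, 1, mt-Cytb, rose and 0 fell, or 0 and 0 adjusted over the list alone (camera adjusted p = 0.705). mt-Cytb did not pass without GPR35-negative replicate 2 or 3 or GPR35-positive replicate 1 (adjusted p = 0.0682, 0.0632 and 0.0856), without filter (0.0679) or with a GC and length trend removed (0.192). Other members passed in single settings: mt-Nd6 was lower with that trend removed (adjusted p = 0.00147), mt-Nd2 lower without GPR35-negative replicate 3 (0.0121) and mt-Atp6 higher without GPR35-negative replicate 1 (0.0455). The list's summed level was 2374, 1893 and 1323 FPKM in the GPR35-negative libraries and 1778 ± 40.3 FPKM (SD, n = 3) in the GPR35-positive ones. In all lists for which no second pair of counts is given, the counts adjusted over the list alone were the same as those over all genes tested. Of the 31 lists, 20 passed camera with a preset correlation of 0.01, 0 with an estimated correlation and 29 in fry, which asks only whether a list's genes move one way on balance.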

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

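Removing a GC and length trend was chosen after the data were seen; the other settings were planned. Genes higher numbered 2342 and ranged from 2293 to 3440 over the other scalings, filters, pseudocount and voom. Genes lower numbered 4575 and ranged from 2401 with median-of-ratios scaling to 4861. That scaling moved the median log2 fold change of all genes from −0.19 to −0.03. Whether the falls no longer called were smaller than this shift was not tested. Requiring at least 2-fold left 1108 higher and 21 lower, by construction. Leaving out 1 library gave 2176 to 2362 higher, 3900 to 4558 lower, 19 to 21 lists and a Gpr35 log2 fold change of 2.98 to 3.17. Gene lists past the threshold numbered 20, and 0 with an estimated correlation, against 29 in fry. Of the 20, the arachidonic acid, G protein, cell cycle and dendritic cell lists had negative estimates, of −0.022, −0.005, −0.03 and −0.193. Their camera adjusted p with those estimates was 0.111, 0.111, 0.119 and 0.111. For these lists this argues against correlation between genes as the reason for the lost call. The other lists that lost it had positive estimates, so for them it stays open. That setting of camera also takes its degrees of freedom from the few libraries instead of from the genes tested. Its adjusted p-values therefore cannot separate correlated genes from a small number of libraries. No other cause was tested. The planned count tests other than voom were not run. No gene called as deposited was called in the opposite direction in any of these settings, and 4743 of the 6917 calls were kept with median-of-ratios scaling. Gpr35 ranged from 2.98 to 3.70, the latter with voom, and passed in every setting. With the replicate number as a paired term (replicate block), 2365 genes were higher, 4633 lower, 20 lists passed and Gpr35 was at 3.05 (adjusted p = 7.61e-07). The deviations of same-numbered libraries correlated at −0.002, 0.4 and −0.064, and those of other pairs across the groups at −0.373 to 0.248. Deviations from a mean of 3 libraries depend on each other, so these values cannot tell whether the numbers pair the samples. Depth limits mainly genes below 1 FPKM, such as Nos2.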

Other observations

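The scaling to neutrophil markers, the tests of cell type shares, the ratios to neutrophil markers and the removal of a GC and length trend were chosen after results had been seen; the splits and the median-of-ratios scaling were planned. Log2 ratios below are of mean FPKM, without a pseudocount unless one is named. The comparison of macrophage with neutrophil markers was first made on log2 ratios over the tested members alone. There macrophage markers came out higher, with a median of 4.66 against 3.27. On the log2(FPKM + 1) scale their median was lower, at 2.31 against 2.73. The comparison was redone over all members with a pseudocount of 0.1, because a filter on low values favours rises. The count of macrophage markers beyond the highest neutrophil marker was added after both, with its bounds chosen when the C1q levels were known. To see which genes differed beyond the neutrophil markers, each library was scaled to the 18 mature neutrophil markers, whose level differed 9.37-fold between groups. On that scale the checkpoint ligand gene Cd274, Ptgs2, Isg15 and H2-Ab1 lay between −0.15 and 0.15 and did not pass. The lists they came from held more members lower than higher. Of 23 interferon-stimulated genes 0 were higher and 13 lower (median −0.95), and of 18 antigen presentation genes 2 and 14 (median −1.12). Of 19 long-lived tumour neutrophil genes 2 were higher and 12 lower (median −1.42), and of 14 suppressive myeloid genes 4 and 6 (median −0.16). All 15 NF-kappaB feedback genes were lower (median −1.46). Arg1, Mmp12, Ccl24 and the 3 C1q genes stayed higher, by 1.64 to 1.91, and so did Cd36 at 1.16, Wfdc17 at 0.71 and Bcl2a1a at 0.72. This scale assumes that the marker genes are equally expressed per neutrophil in both groups, and it lowers nearly all genes: 180 were higher and 9499 lower, with a median of −2.79.

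The GPR35-positive libraries showed many large rises beside small falls. Under median-of-ratios scaling 1257 genes were at least 2-fold higher and 0 at least 2-fold lower. That scaling moved the median of all genes upward, from −0.19 to −0.03, so it was bound to keep the excess of large rises. It therefore cannot decide whether library scaling is a cause. After a GC and length trend was removed, 96.7% of the genes at least 2-fold higher stayed so, which argues against GC and length as the whole cause. A lower hepatoma share that raises every other cell type alike is argued against by the T and NK markers, whose median log2 ratio lay 3.465 below that of the neutrophil markers. A larger share of myeloid RNA against hepatoma RNA may be part of the pattern. Hepatoma markers would then fall by a like factor. In the data 11 abundant hepatocyte and hepatoma markers shared a median log2 ratio of −0.61 (SD 0.19). How cells were sorted is not given in the sources used here, so how hepatoma RNA came into the libraries is unknown. A difference between GPR35-positive and GPR35-negative neutrophils stays open, untested. Of the 10 splits of the 6 libraries, 1, the real one, gave as many as 6917 genes and the highest other gave 0; the splits are too few for a share under 0.05.

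Gpr35 rose towards the upper end of the neutrophil markers. Its log2 ratio of 3.69 lay 0.42 above the median of the 18 markers. Those markers ran from 0.16 to 4.06 with an SD of 0.84, which the lowest, Padi4, widens. A larger neutrophil share alone is thus a candidate explanation for most of the Gpr35 rise. Relative to the markers Gpr35 was still higher, at 0.41 (SE 0.12, adjusted p = 0.00597), as was the marker Fpr1 at 0.39, and 9 of the 18 markers themselves passed in one direction or the other. Per 100 FPKM of S100a8, Gpr35 was at 0.301 ± 0.0509 and 0.386 ± 0.0645 FPKM (SD, n = 3 each), groups that overlapped (exact two-sided permutation p = 0.2, adjusted p = 0.2 over 3 ratios; the smallest possible is 0.1), while against the median marker the groups were separated, with a difference of 0.57 on the log2 scale (exact permutation p = 0.1, adjusted p = 0.15). More Gpr35 per neutrophil, as the labels would have it, stays open beside a larger neutrophil share. Bulk RNA does not assign Gpr35 reads to neutrophils. A source in other cells, such as macrophages, stays open too and was not tested.

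The 3 C1q genes were among the largest rises, and C1qb, chosen for its rise and the other of the 3 ratios tested, rose by 2.03 more on the log2 scale than the median neutrophil marker (exact permutation p = 0.1, adjusted p = 0.15). Of the 20 macrophage markers above 0, 6 rose further than all 18 neutrophil markers, whose highest log2 ratio was 3.81, even between the least separated libraries. These were C1qa, C1qb, C1qc, Adgre1, Ms4a7 and Cd5l (pseudocount 0.1, one-sided permutation p = 0.0136 over 100000 resamples of genes, which are not independent). Of the 6, only the 3 C1q genes were at least 1 FPKM in each GPR35-negative library. There Adgre1, Ms4a7 and Cd5l were as low as 0.353, 0.157 and 0.156 FPKM. For the C1q genes, themselves singled out by their rise, this argues against a larger neutrophil share alone, as far as the markers track that share. For the list as a whole that share and more macrophage RNA cannot be told apart. This is because 7 of the 20 markers lay below the filter and the members differed widely. With a pseudocount of 0.1, their median log2 ratio differed by −0.51 from that of the neutrophil markers (two-sided permutation p = 0.196). The SD was 1.96 for the macrophage markers and 0.84 for the neutrophil markers. More macrophage RNA in the GPR35-positive libraries is a candidate explanation. Without a filter 14 of 20 markers were higher there, and C1qb, C1qa and C1qc were at 307, 173 and 183 FPKM. How cells were sorted is not given in the sources used here, so a sort cannot be weighed against macrophage RNA. Neutrophils that express these genes themselves, more so in the GPR35-positive group, stay open too, since bulk RNA does not assign transcripts to cells.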
